A study of Homo sapiens with 6 samples.

How the data were processed

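The series holds 6 single-colour arrays (Cy3) of total RNA from A1-2 breast cancer cells, 3 treated with 100 nM dexamethasone and 3 with 0.1% ethanol for 8 h after 48 h in medium with 5% charcoal-treated serum, per the labels. The labels call the 3 arrays of each group biological replicates, and each labelling started from 500 ng of RNA. The arrays were of Agilent design 014850, with 45015 spots, of which 1639 were controls and 43376 were spots of 41000 probes (264 probes were spotted more than once, up to 10 times). The deposited values were intensity values on a linear scale, made by the authors with Agilent Feature Extraction (9.5 per the submitters' processing notes, 9.5.3.1 per the file headers). Per the file headers, the processed intensity was background-adjusted and detrended within each array, dim spots were given surrogate values, and no scaling between arrays was applied. Surrogates stood on 8.23% to 11.6% of the spots per array. Probe positions in the files refer to the human build hg17, per the file headers. The authors' table of processed values equalled the processed intensity of the same arrays (largest difference 0), on the linear scale and uncentred, with column medians of 161.8 to 192.7, so it served only as an alternative.

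Control spots and spots with an outlier mark (44 to 128 per array) were left out, saturated spots (3 on dexamethasone replicate 2 and 0 on the others) were kept, and spots of a probe were averaged. The log2 processed intensity of each array was set relative to its 75th percentile, which was 1631 to 1789. A probe was tested when it was well above background on all arrays of at least 1 group, and the probe with the highest mean stood for its gene. Of the 41000 probes, 26794 matched a symbol in the RefSeq gene table of assembly GRCh38.p14 (23434 by accession and 3360 by symbol), used only for names, 1653 kept the name in the files and 12553 had no gene name and were tested singly. Of 5806 genes with several tested probes, 1933 had a called probe and 9 had probes called in opposite directions. The noise between spots of a probe within an array had an SD of 0.0656 on the log2 scale, against an SD between replicates of 0.129 for dexamethasone and 0.118 for ethanol. The number of arrays limits the precision of every value, and the median SE of a log2 fold change was 0.136.

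Dexamethasone was compared with ethanol by limma (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all 24614 genes tested and a threshold of 0.05 on the adjusted p. The moderated test had 6.24 degrees of freedom. Where no array of a group was well above background, the change is given as a bound, the mean of the brighter group over the mean, in the dimmer group, of the higher of each array's lowest well-above-background signal and the probe's own signal. Fold intervals at 95% come from the moderated SE. The bounds are ratios of means without such an interval, so they are not guaranteed minimum changes. Slide was tested as a fixed and as a random block and by values within each slide, since each slide held 1 array of each group. The comparison was tested on simulated data with 24600 genes in 3 and 3 arrays, 200 of them changed. Of changes of 0.5, 1 and 2 on the log2 scale, 0%, 76.1% and 97.0% were recovered, with 6 false calls. Far fewer genes changed in the simulation than were called in the data (5039), so the recovered shares do not carry over to the data. Of 100 simulated lists without a shift, 4 had an unadjusted p under 0.05 and 0 were called. The simulated genes were drawn independently, so this does not cover lists whose members move together. In the data the estimated correlation within a list reached 0.718 (interferon-stimulated genes).

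The 29 gene lists, the rule for the named genes, the design and all alternatives but spike-in scaling were fixed before the data were examined. The lists were glucocorticoid-induced genes, inflammatory cytokines and NF-kB and AP-1 targets, interferon-stimulated genes, circadian clock, sodium and potassium transport, MAP kinase and receptor tyrosine kinase feedback inhibitors, metallothioneins and zinc transport, estrogen receptor targets, androgen and progesterone responsive genes, milk proteins and mammary secretory genes, steroid receptors with chaperones and cofactors, DNA replication, mitosis, cell cycle inhibitors and quiescence, apoptosis regulators, cholesterol synthesis, fatty acid and lipid storage, gluconeogenesis and amino acid metabolism, unfolded protein and integrated stress responses, heat shock proteins, hypoxia response, TGF-beta and BMP pathway, Wnt and Notch pathway, adhesion with junction and matrix genes, luminal, basal, fibroblast and leukocyte or endothelial markers, and housekeeping genes. They held 897 distinct members, of which 890 were on the array. A list's shift was tested with camera (two-sided, preset correlation of 0.01, adjusted over the 29 lists), and again with the correlation estimated from the data. The second form takes its degrees of freedom from the arrays rather than the genes, so few lists can pass it here. The test fry was run beside these, and it sets a list against no change, not against the other genes. Members were counted from the gene test and, in a second count, adjusted over the list alone.

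The named genes were the 12 with the largest rise and the 12 with the largest fall among called genes with a proper symbol and non-overlapping groups, up to 4 called members per list with the largest change, or up to 2 tested members where none was called, and 14 genes always reported. Further members, named where a count was 5 or fewer, and the Kruppel-like factor genes not yet named were chosen after their values were seen, 49 of the 179 named genes in all. Some genes that these rules take are not reported here. The alternatives were quantile and median normalization, normexp background correction (offset 50) of the mean and local background intensities followed by quantile normalization, no filter on dim probes or one over all 6 arrays, outlier spots kept, the mean of a gene's probes, eBayes with an intensity trend or robust settings, slide as a block, replicate number as a block, the authors' value table, each array left out in turn, a 1.5-fold threshold, an adjusted p of 0.01, the other list tests, and lists without members shared with the glucocorticoid-induced genes. Scaling to 8 spike-in probes was added after seeing the data, in which these probes differed by 0.09 between groups on the log2 scale. Analyses used R 4.3.3 with limma 3.58.1, and figures Python 3.11.15 with matplotlib 3.10.9.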

Results

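Gene expression was measured in A1-2 cells, a derivative of the T47D breast cancer line that carries an introduced glucocorticoid receptor. The cells received either 100 nM dexamethasone, a synthetic glucocorticoid, or the vehicle (0.1% ethanol), and RNA was taken after 8 h. Each group held 3 biological replicates, and each RNA was hybridised to 1 single-colour array with 41000 probes. The median processed intensity was 181 to 214 per array, and 77.6% to 82.6% of the probes were well above background. Each of 3 slides carried 1 array of each group. Dexamethasone replicate 1 shared a slide with ethanol replicate 2, dexamethasone replicate 3 with ethanol replicate 1, and dexamethasone replicate 2 with ethanol replicate 3. The Pearson correlation across genes, which are not independent replicates, was 0.991 to 0.996 between arrays of a group and 0.964 to 0.977 between arrays of different groups. The comparison asks which transcripts the activated receptor had changed at this time. Changes are given as log2 fold change ± SE, dexamethasone over ethanol, from 3 arrays against 3.

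Of 24614 genes tested, 5039 (20.5%) changed, of which 2331 were raised and 2708 were lowered. The large changes were mostly rises. Fold thresholds here and below were applied to fitted values, also for genes whose change has only a bound. By these, at least 2-fold changes comprised 1241 raised and 722 lowered genes, at least 8-fold changes 273 raised and 5 lowered genes, and at least 16-fold changes 154 raised genes and 0 lowered ones. Of the genes raised at least 2-fold, 145 were not well above background on any ethanol array. The groups did not overlap for 37.4% of the genes tested, where chance gives 10% for genes admitted without regard to group. The filter also admitted dim genes well above background in only 1 group, so the chance level here may differ. Within slides 1, 2 and 3, 1676, 1327 and 1729 genes were raised at least 2-fold and 1252, 1086 and 1167 were lowered at least 2-fold. The excess of lowered over raised genes lay among changes under 2-fold (1090 raised and 1986 lowered) and moved with the scaling. Raised genes made up 46.3% of the changed genes in the 75th percentile scaling, 51.8% when arrays were scaled by their medians and 34.2% when they were scaled to spike-in probes. With slide as a block, 1897 genes were raised and 1714 lowered. Leaving out 1 array moved the number of changed genes to 3032 (without dexamethasone replicate 1), 2969 (dexamethasone replicate 2), 2732 (ethanol replicate 1) and 2718 (ethanol replicate 2). The raised genes then numbered 1523 without dexamethasone replicate 2, 1535 without ethanol replicate 1 and 1508 without ethanol replicate 2. The lowered genes numbered 1462 and 1446 without dexamethasone replicates 1 and 2, and 1197 and 1210 without ethanol replicates 1 and 2.

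**Figure D1:**
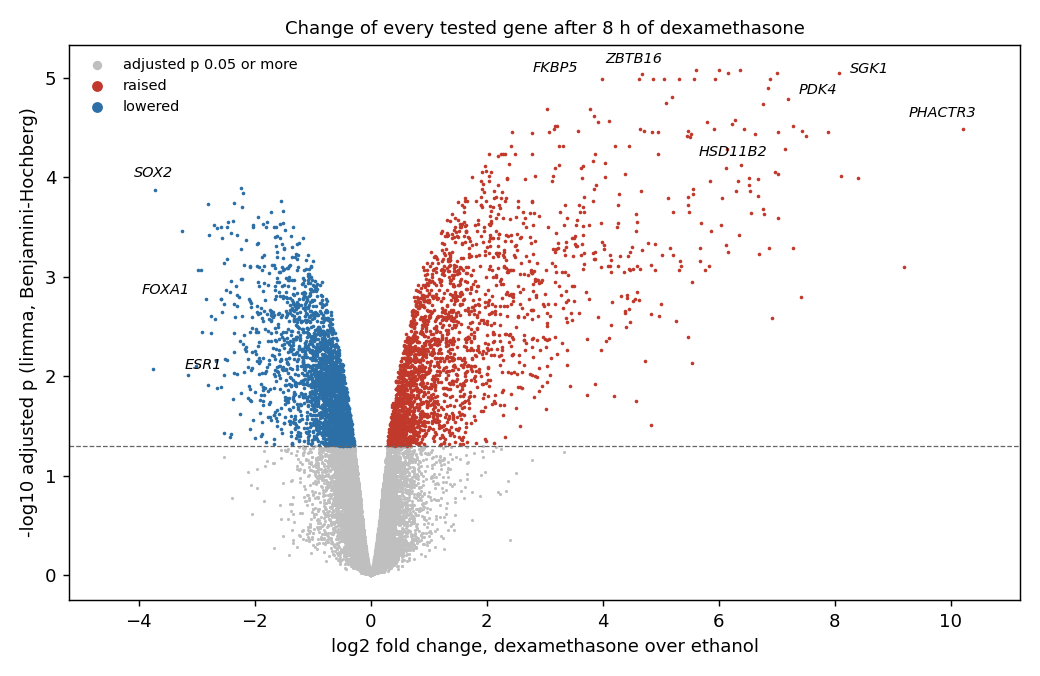
Each point is 1 of the 24614 tested genes, with the log2 fold change (dexamethasone over ethanol, 3 arrays each) on the horizontal axis and −log10 of limma's adjusted p on the vertical axis, where red marks the 2331 raised genes, blue the 2708 lowered genes, grey the rest and the dashed line an adjusted p of 0.05. Rises extend to 10.21 (PHACTR3), and among the labelled falls SOX2 lies lowest at −3.71; for genes not well above background in 1 group the plotted value is the fitted one, not a bound.

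Among the 12 largest rises, SGK1, the serum- and glucocorticoid-regulated kinase (probe on chromosome 6, 134532349 to 134532408, hg17), rose 268-fold (95% interval 207 to 348, adjusted p = 8.81e-06). PDK4, a kinase that restrains pyruvate oxidation, rose by 7.18 ± 0.19, B3GAT1, a glucuronyltransferase, by 7.02 ± 0.41, and PGC, which encodes a digestive protease precursor, by 7.42 ± 0.75. PHACTR3, a phosphatase and actin regulator, rose by 10.21 ± 0.33 and ADAMTS8, a secreted metalloprotease, by 9.20 ± 0.77, but each was well above background on 1 of 3 ethanol arrays. The remaining 6 were not well above background on any ethanol array and rose at least 151-fold (CALB1, a calcium-binding protein), 94.3-fold (NANOG, whose probe may also read pseudogene copies), 85.2-fold (IGFBP1, a secreted binder of insulin-like growth factors), 67.8-fold (PNLIP, a lipase), 47.8-fold (SLC6A3, a dopamine transporter) and 45.8-fold (AKR1D1, a steroid reductase). The bounds leave out sampling error. Those of CALB1, NANOG and IGFBP1 lie above the lower 95% limits of their fitted folds (149, 76.8 and 62.9). Those of PNLIP, SLC6A3 and AKR1D1 lie below such limits. The 12 were ranked by fitted values, so the place of these 6 is not secured by their bounds. All these bounds but that of CALB1 lie below the rises of IP6K3 (118-fold) and SERPINA3 (116-fold), measured in both groups and outside the 12. Among the 12 largest falls, SOX2, a stem cell transcription factor (chromosome 3, 182913448 to 182913507, hg17), was 13.1-fold lower (95% interval 9.65 to 17.8, adjusted p = 0.000133). PLCH1, a phospholipase C, fell by 3.26 ± 0.21 on the log2 scale, KALRN, a signalling protein of neurons, by 2.81 ± 0.15, and RNF43, a ubiquitin ligase that restrains Wnt signalling, by 2.66 ± 0.41. CXXC4 (−3.01 ± 0.48), TXLNB (−2.98 ± 0.26), DSCAM (−2.80 ± 0.51), FAM167A (−2.78 ± 0.19), TESK2 (−2.76 ± 0.32) and PCED1B (−2.70 ± 0.17) were also lowered. The receptor genes DRD1 and HRH1 were not well above background on any dexamethasone array and were at least 2.35-fold and 1.47-fold lower. Both rank among the 12 by fitted values only. FOXA1 and KCNC1, measured in both groups and outside the 12, were each 5.98-fold lower. The fitted values of ADAMTS8 (8.44 without ethanol replicate 2, 10.07 without ethanol replicate 3), PGC (8.33 without ethanol replicate 3) and IGFBP1 (6.68 without ethanol replicate 1) depended on 1 array by over 1.5-fold, with each call kept. Without ethanol replicate 1 another probe stood for HRH1, with a fitted value of −1.84. The reported probe had fitted values of −2.58 on the same arrays and −2.65 on all 6, for a fall that has only a bound. Normexp background correction moved 44 of the 179 named genes by over 1.5-fold, among them PHACTR3 to 7.26, SGK1 to 7.24 and SOX2 to −2.67 (at another probe), and averaging probes gave −1.48 for KALRN, 6.54 for PDK4 and 6.15 for the fitted value of AKR1D1.

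Of 51 tested glucocorticoid-induced genes, 39 rose, 2 fell and 10 were not called (43 raised and 2 lowered when adjusted over the list alone). The median change was 2.38, and 36 members rose at least 2-fold. FKBP5, a co-chaperone that lowers receptor affinity (chromosome 6, 35649906 to 35649965, hg17), rose 15.8-fold (95% interval 13.5 to 18.4, adjusted p = 1.03e-05). TSC22D3, the anti-inflammatory leucine zipper protein GILZ, rose by 3.67 ± 0.19, PER1, a clock repressor, by 3.32 ± 0.12, NFKBIA, the inhibitor of NF-kB, by 1.93 ± 0.09, and SERPINA3, an acute phase protease inhibitor, by 6.86 ± 0.50. The lowered members, GADD45A (−1.64 ± 0.12), a damage-responsive growth inhibitor, and TNFAIP2 (−1.66 ± 0.11), an NF-kB target, were chosen after their values were seen. The list shifted upward against the other genes (camera, adjusted p = 6.35e-29; adjusted p = 0.125 with an estimated correlation), with slide as a block (adjusted p = 3.29e-28) and with medians of 2.62, 2.26 and 2.43 within slides 1 to 3. Across the 29 lists, 11 shifted with the preset correlation (10 up, 1 down) and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. Among the 11, the estimate was below the preset 0.01 for feedback inhibitors (−0.032), cell cycle inhibitors (−0.012) and fatty acid genes (−0.010), and above it for the rest. The lists below the preset lost their calls as well, so correlation between members cannot alone account for the losses. The test fry asks another question, whether a list's members shifted together up or down, set against no change rather than against other genes. It passed 16 lists. These left out 1 of the 11, interferon-stimulated genes (adjusted p = 0.0652), and held 6 that camera did not call, namely steroid receptors and cofactors (0.00933), circadian clock (0.016), apoptosis (0.016), adhesion (0.0327), Wnt and Notch (0.0395) and heat shock genes (0.0473). Regrouping the 6 arrays in the other 9 ways called 3 to 13 lists. Each regrouping keeps part of the treatment difference between its sides, so these counts do not measure chance.

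**Figure D2:**
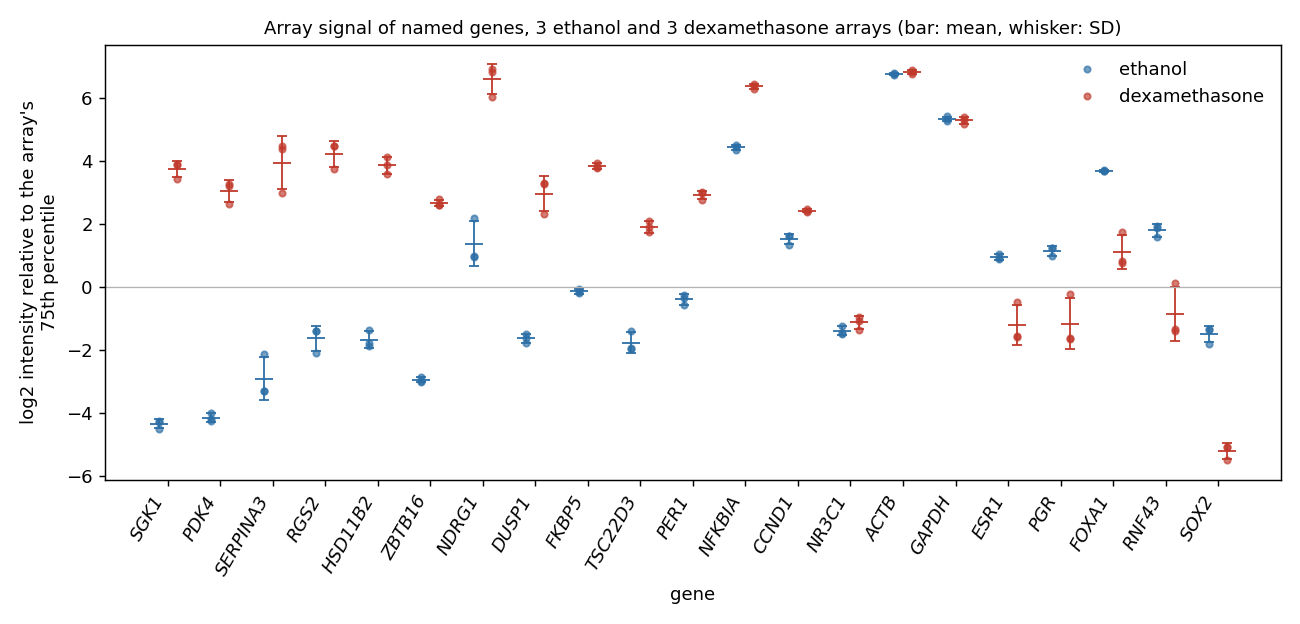
Each point is 1 array's log2 intensity relative to that array's 75th percentile for each named gene shown, ethanol in blue and dexamethasone in red, with the mean as a bar and the SD of 3 arrays as a whisker. SGK1 had means of −4.34 and 3.73, FOXA1 of 3.68 and 1.10, and ACTB of 6.75 and 6.82 in ethanol and dexamethasone; heights compare groups within a gene, not genes with each other.

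Genes known to respond to androgen or progesterone also rose, with 19 of 33 raised, 2 lowered and 12 not called (20 raised and 3 lowered when adjusted over the list alone). ZBTB16, a transcriptional repressor, rose by 5.61 ± 0.10, HSD11B2, which inactivates cortisol, by 5.53 ± 0.19, and NDRG1, a stress-responsive gene, by 5.21 ± 0.40. STEAP4, a metalloreductase, was not well above background on any ethanol array and rose at least 18.3-fold. The lowered members EDN1 (−1.18 ± 0.17), a vasoconstrictor peptide, and TMPRSS2 (−0.91 ± 0.13), a serine protease, were chosen after their values were seen. The median change was 0.91 and 3 members are also on the glucocorticoid-induced list (camera, adjusted p = 4.38e-10, adjusted p = 0.125 with an estimated correlation, 8.95e-10 with slide as a block, within-slide medians 1.01, 1.21 and 0.59). Of 23 milk and mammary secretory genes, 6 rose and 0 fell (7 and 1 when adjusted over the list alone), led by the prolactin-signalling factors STAT5A (4.65 ± 0.15) and STAT5B (1.56 ± 0.10), the lipid droplet coat PLIN2 (1.46 ± 0.10) and SCGB2A1 (2.61 ± 0.43), a secretoglobin well above background on 2 of 3 ethanol arrays. Their median was 0.12 (camera, adjusted p = 0.0159, adjusted p = 0.536 with an estimated correlation, 0.0253 with slide as a block, within-slide medians 0.03, 0.25 and 0.27). The list member PRLR had probes called in opposite directions when probes were tested singly (0.35 ± 0.09 and −0.49 ± 0.12).

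Feedback inhibitors of MAP kinase and receptor tyrosine kinase signalling moved both ways, with 12 of 25 raised, 4 lowered and 9 not called (12 and 5 when adjusted over the list alone). The raised members included DUSP1, a MAP kinase phosphatase (4.59 ± 0.28), RGS2, a brake on G protein signalling (5.85 ± 0.27), RASD1, a Ras-related GTPase (5.80 ± 0.17), and SPRY1, a Sprouty protein (2.64 ± 0.35). The lowered members DUSP10 (−1.83 ± 0.17) and DUSP4 (−1.19 ± 0.21), both phosphatases, TRIB3 (−0.94 ± 0.20), a pseudokinase, and CBL (−0.67 ± 0.11), a ubiquitin ligase, were chosen after their values were seen. CBL lost its call when probes were averaged (−0.66, adjusted p = 0.0525). The call of TRIB3 was lost with slide as a block and on leaving out any 1 array but dexamethasone replicate 3 (−1.02 to −0.81). The median was 0.47 (camera, adjusted p = 0.00335, adjusted p = 0.125 with an estimated correlation, 0.0081 with slide as a block, within-slide medians 0.52, 0.50 and 0.54), and the shift was no longer called without the members shared with the glucocorticoid-induced list (adjusted p = 0.103).

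Sodium and potassium transport genes had 11 of 30 members raised, 1 lowered and 18 not called (11 and 2 when adjusted over the list alone). Beside SGK1 and HSD11B2, KCNMA1, a calcium-activated potassium channel, rose by 3.23 ± 0.23, the highest of 5 probes (1.13 to 3.23), which averaged 2.52. The median was −0.05 while the mean was 0.89 and the shift upward (camera, adjusted p = 0.0159, adjusted p = 0.232 with an estimated correlation, 0.0275 with slide as a block, within-slide medians −0.09, 0.26 and −0.03). The shift was lost without dexamethasone replicate 3 (adjusted p = 0.0874) and without the members shared with the glucocorticoid-induced list (adjusted p = 0.371).

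Inflammatory cytokines and targets of NF-kB and AP-1 were split, with 6 of 36 raised, 9 lowered and 21 not called (6 and 13 when adjusted over the list alone). FOS, an AP-1 subunit, rose by 3.76 ± 0.23 and PLAUR, the urokinase receptor, by 2.94 ± 0.27, and TLR2, a receptor for bacterial lipoproteins, rose at least 4.28-fold from a level not well above background on any ethanol array. IER3, an early response gene, fell by 2.36 ± 0.39. No shift of the list was called (camera, adjusted p = 0.376, median −0.28, within-slide medians −0.35, −0.23 and −0.09). Interferon-stimulated genes moved downward where they moved, with 0 of 36 raised and 11 lowered (12 when adjusted over the list alone). IFIT3 fell by 1.45 ± 0.20, IFI44L by 1.41 ± 0.13 and OASL by 1.35 ± 0.19, all of them antiviral response genes. IFIT2 (−1.88 ± 0.43) lost its call with slide as a block and on leaving out any 1 array but ethanol replicate 3 (−2.03 to −1.60). The median was −0.34 (camera, adjusted p = 4.56e-05, adjusted p = 0.707 with an estimated correlation, 5.93e-05 with slide as a block, within-slide medians −0.41, −0.64 and −0.03). Against the mean of the ethanol arrays, the list's median was −0.27, −0.28 and −0.50 on dexamethasone arrays 1 to 3, and 0.14, 0.13 and −0.25 on ethanol arrays 1 to 3, so ethanol replicate 3 lay beside dexamethasone replicates 1 and 2.

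Among steroid receptors and their chaperones and cofactors, 1 of 36 members rose and 8 fell (2 and 8 when adjusted over the list alone). FOXA1, a pioneer factor of luminal cells, fell by 2.58 ± 0.27, PGR, the progesterone receptor, by 2.31 ± 0.39 and ESR1, the estrogen receptor, by 2.16 ± 0.30. A second FOXA1 probe gave −2.57, and 2 further ESR1 probes gave −1.45 and −0.83 (−1.48 with probes averaged). NCOA1, a coactivator chosen after its value was seen, rose by 0.84 ± 0.11. NR3C1, the glucocorticoid receptor gene, was not called (0.27 ± 0.14, adjusted p = 0.26), and a second probe gave 0.22. The labels do not say whether these probes read the introduced receptor, so both values may cover the cells' own gene alone. The shift of the whole list was not called (camera, adjusted p = 0.339, median −0.03, within-slide medians −0.07, −0.10 and −0.12). Of 40 estrogen receptor targets, 5 rose and 5 fell (6 and 5 when adjusted over the list alone). MYB, a proto-oncogene, fell by 1.98 ± 0.29, while CCN5, a matricellular protein, rose by 3.25 ± 0.31 and CCND1, cyclin D1, by 0.89 ± 0.11. SIAH2 (1.56 ± 0.12), GREB1 (1.11 ± 0.17), CA12 (0.71 ± 0.16), RERG (−1.37 ± 0.18) and SUSD3 (−1.17 ± 0.21) also changed and were chosen after their values were seen. CA12 lost its call on leaving out any 1 array but ethanol replicate 3 (0.60 to 0.79) and when probes were averaged. MYC was not called (0.86 ± 0.25, adjusted p = 0.0602, 0.00456 to 0.182 over the other fits that kept its probe). It passed with median scaling (0.0494), normexp background correction (0.0451), an intensity trend (0.0327) and the replicate number as a block (0.0382), and without ethanol replicate 3 (1.15). A second MYC probe gave −0.00, and with probes averaged MYC was not called (0.43). Camera called no shift (adjusted p = 0.832, median −0.14, within-slide medians −0.17, 0.20 and −0.54).

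Of 21 luminal epithelial markers, 3 rose and 7 fell (3 and 8 when adjusted over the list alone). Beside FOXA1 and ESR1, SPDEF, a luminal transcription factor (−1.55 ± 0.33), was lowered, a call lost on leaving out any 1 array but dexamethasone replicate 3 (−1.58 to −1.35). AGR3, a secretory pathway isomerase, rose by 1.33 ± 0.23, as did KRT7 (0.82 ± 0.14) and MUC1 (0.42 ± 0.10), both chosen after their values were seen. MUC1 lost its call with slide as a block and on leaving out any 1 array but ethanol replicate 3 (0.38 to 0.45). The list was not called (camera, adjusted p = 0.0769, median −0.17, within-slide medians −0.32, −0.40 and −0.28), but passed in 7 other fits, with quantile normalization (0.0439), normexp background correction (0.0279), no filter on dim probes (0.0362), an intensity trend (0.0456) and slide as a block (0.0387), and without dexamethasone replicate 3 (0.00282) or ethanol replicate 3 (0.0356). With an estimated correlation the adjusted p was 0.707. Of 20 basal and myoepithelial markers, 6 rose and 1 fell (6 and 1 when adjusted over the list alone). EGFR rose by 2.83 ± 0.20, and the basal keratin KRT5 by 5.47 ± 0.72 (6.33 without dexamethasone replicate 3), with 2 of 3 ethanol arrays well above background. KRT16 (2.50 ± 0.53), whose probe may read related keratins, lost its call without dexamethasone replicates 1 or 2 or ethanol replicates 1 or 3 (2.11 to 2.63) and when probes were averaged. TP63, a basal lineage factor (−1.84 ± 0.36), lost its call without dexamethasone replicates 1 or 2 or ethanol replicate 2 (−1.92 to −1.64). That list's shift was not called (camera, adjusted p = 0.218, median 0.12, within-slide medians −0.16, −0.32 and 0.40).

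Of 15 fibroblast and mesenchymal markers, 3 rose and 2 fell (4 and 2 when adjusted over the list alone). CDH2, N-cadherin, rose at least 17.8-fold from a level not well above background on any ethanol array, and SNAI2, a repressor of epithelial genes, rose by 1.48 ± 0.26. The related SNAI1 (1.37 ± 0.28) lost its call on leaving out dexamethasone replicate 1 or 2 or ethanol replicate 1 or 2 (1.18 to 1.35). TWIST1, another mesenchymal transcription factor, fell by 2.42 ± 0.22 (−4.14 at a second probe, −3.28 with probes averaged). COL1A1 (−0.52 ± 0.12), chosen after its value was seen, lost its call with slide as a block and on leaving out any 1 array but ethanol replicate 3 (−0.53 to −0.45). A shift of these genes was not called (camera, adjusted p = 0.256, median 0.05, within-slide medians 0.10, 0.26 and 0.20), but was called without dexamethasone replicate 3 (0.0436) and with no filter on dim probes (0.0314). Of 16 genes on the leukocyte and endothelial marker list, 2 rose and 0 fell, over all genes and when adjusted over the list alone. HBA1 (2.64 ± 0.35) is a red cell globin gene placed on that list, not a leukocyte or endothelial marker. Its probe may also read the near-identical HBA2. The other was CSF1R (0.75 ± 0.18), which lost its call with slide as a block and without dexamethasone replicate 1 or any 1 ethanol array (0.71 to 0.83). That list's shift was not called (camera, adjusted p = 0.218, median 0.10, within-slide medians −0.04, 0.32 and 0.16), but passed without dexamethasone replicate 3 (0.0498).

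DNA replication genes changed little, with 6 of 46 raised, 0 lowered and 0 changed at least 2-fold (2 raised and 0 lowered when adjusted over the list alone). The counts moved with the scaling, to 4 raised and 1 lowered with quantile normalization, 6 and 2 with normexp and 2 and 1 with spike-in scaling. ORC1, an origin recognition subunit, rose by 0.78 ± 0.11 and GINS3, a helicase component, by 0.54 ± 0.09. CDC7, a replication kinase (0.65 ± 0.17; 0.53 to 0.69), and POLE2, a polymerase subunit (0.52 ± 0.12; 0.45 to 0.53), lost their calls with slide as a block and on leaving out any 1 array but dexamethasone replicate 3. The list's shift (median 0.10; camera, adjusted p = 0.0151; adjusted p = 0.386 with an estimated correlation; 0.0275 with slide as a block; within-slide medians 0.06, 0.15 and 0.03) was lost without dexamethasone replicate 3 (0.0706), with quantile normalization (0.0626) and with spike-in scaling (0.0766). Of 47 mitotic genes, 3 rose and 2 fell (3 and 1 when adjusted over the list alone, 2 to 3 and 0 to 6 over the scalings), and 0 changed at least 2-fold. MKI67, a proliferation marker, rose by 0.80 ± 0.08 and CDC20, an activator of the anaphase-promoting complex, by 0.56 ± 0.09. KIF23 (0.38 ± 0.09; 0.33 to 0.41), chosen after its value was seen, and ECT2 (−0.46 ± 0.10; −0.47 to −0.41) lost their calls with slide as a block and on leaving out any 1 array but dexamethasone replicate 3, and TOP2A (−0.41 ± 0.11; −0.47 to −0.33) with slide as a block and on leaving out each of the 6. The shift of the mitotic list was not called (camera, adjusted p = 0.936, median −0.06, within-slide medians −0.13, −0.07 and 0.03).

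Cell cycle inhibitors and quiescence genes had 13 of 36 members raised, 3 lowered and 20 not called (14 and 5 when adjusted over the list alone). The forkhead factors FOXO4 and FOXO1 rose by 4.26 ± 0.35 and 3.99 ± 0.28, the kinase inhibitor CDKN2B by 3.04 ± 0.54 and KLF4, an antiproliferative transcription factor, by 2.61 ± 0.28. Averaging probes gave 1.99 for FOXO4. GADD45A fell, as did GAS2L1 (−0.58 ± 0.15; −0.65 to −0.50) and CDKN2D (−0.49 ± 0.11; −0.49 to −0.41), which were chosen after their values were seen and lost their calls with slide as a block and on leaving out any 1 array but dexamethasone replicate 3. The median was −0.00 while the mean was 0.68 and the shift upward (camera, adjusted p = 0.0135, adjusted p = 0.136 with an estimated correlation, 0.0218 with slide as a block, within-slide medians 0.03, 0.17 and 0.04). Without the members shared with the glucocorticoid-induced list it was lost (adjusted p = 0.135). Of 37 apoptosis regulators, 9 rose and 2 fell (9 and 4 when adjusted over the list alone). BIRC3, an inhibitor of apoptosis, rose by 5.51 ± 0.20 and CFLAR, which blocks caspase 8 activation, by 1.54 ± 0.16, whereas the pro-apoptotic BIK and the death ligand TNFSF10 fell by 1.52 ± 0.20 and 1.49 ± 0.20. As a list, their shift was not called (camera, adjusted p = 0.218, median 0.05, within-slide medians −0.12, 0.05 and 0.06).

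Of 39 fatty acid and lipid storage genes, 11 rose and 4 fell (15 and 5 when adjusted over the list alone). Beside PDK4, ACSL1, which activates long-chain fatty acids, rose by 3.39 ± 0.20 and ELOVL5, an elongase, by 2.12 ± 0.11. The lowered members, chosen after their values were seen, were PPARGC1A (−1.65 ± 0.16), a coactivator of oxidative metabolism, the acyltransferases GPAT3 (−1.17 ± 0.18) and AGPAT2 (−0.81 ± 0.11), and CPT1A (−0.42 ± 0.10), the mitochondrial carnitine palmitoyltransferase. CPT1A lost its call with slide as a block and without dexamethasone replicate 1 or 2 or ethanol replicate 1 or 2 (−0.42 to −0.36). The median was 0.29 (camera, adjusted p = 0.000416, adjusted p = 0.125 with an estimated correlation, 0.000475 with slide as a block, within-slide medians 0.12, 0.39 and 0.25). Of 28 cholesterol synthesis genes, 8 rose and 7 fell (8 and 9 when adjusted over the list alone), with 8 and 4 under median scaling and 3 and 8 under spike-in scaling. NSDHL and CYP51A1, sterol synthesis enzymes, rose by 1.23 ± 0.16 and 0.68 ± 0.09. MSMO1 (0.66 ± 0.16) lost its call with slide as a block and on leaving out any 1 array but dexamethasone replicate 3 (0.53 to 0.72). No shift of the list was called (camera, adjusted p = 0.665, median −0.01 and mean 0.07, within-slide medians −0.09, 0.22 and −0.11).

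Genes of gluconeogenesis and amino acid metabolism were evenly split in the reported scaling, with 6 of 40 raised and 6 lowered (8 and 8 when adjusted over the list alone). Quantile normalization, with or without normexp, gave 7 and 7, median scaling 6 and 4, and spike-in scaling 5 and 8. GLUL, glutamine synthetase, rose by 2.80 ± 0.21 and SLC2A1, a glucose transporter, by 1.67 ± 0.16, whereas PSPH, the last enzyme of serine synthesis, fell by 1.72 ± 0.10 and SLC7A11, a cystine transporter, by 1.62 ± 0.26. Further PSPH probes gave −1.68 and −0.02, the latter not called. The shift of the whole list was not called (camera, adjusted p = 0.985, median −0.16, within-slide medians −0.22, 0.22 and −0.41). Of 31 hypoxia response genes, 11 rose and 1 fell (14 and 2 when adjusted over the list alone). LOX, which crosslinks collagen, rose by 3.96 ± 0.57 (4.66 without dexamethasone replicate 3) and CA9, a carbonic anhydrase, rose 8.57-fold (95% interval 3.90 to 18.8), beside NDRG1 and the glucose transporter SLC2A3, which rose at least 6.99-fold from a level not well above background on any ethanol array. INSIG2, a sterol sensor chosen after its value was seen, fell (−0.55 ± 0.12) and lost its call without dexamethasone replicate 1 or 2 or ethanol replicate 1 or 2 (−0.58 to −0.48). The median was 0.39 (camera, adjusted p = 3.55e-05, adjusted p = 0.207 with an estimated correlation, 2.05e-05 with slide as a block, within-slide medians 0.34, 0.70 and 0.18). Of 16 metallothionein and zinc transport genes, 4 rose (4 to 7 over the scalings) and 0 fell, and 12 rose when adjusted over the list alone. The zinc importers SLC39A14 and SLC39A8 rose by 2.42 ± 0.26 and 1.09 ± 0.16. The metal-binding MT1X (0.58 ± 0.12) and MT1H (0.56 ± 0.11), whose probes may read related metallothioneins, lost their calls with slide as a block and without ethanol replicate 1 or 3, and MT1X also without dexamethasone replicate 2 (0.55 to 0.61) and MT1H without dexamethasone replicate 1 (0.52 to 0.60). That median was 0.38 (camera, adjusted p = 3.55e-05, adjusted p = 0.125 with an estimated correlation, 5.93e-05 with slide as a block, within-slide medians 0.20, 0.54 and 0.40).

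Among 24 circadian clock genes, 6 rose and 4 fell (7 and 6 when adjusted over the list alone). Beside PER1, the repressor CRY2 rose by 1.75 ± 0.08, while TEF, an output transcription factor, and NR1D1, a nuclear receptor of the clock, fell by 1.86 ± 0.18 and 1.33 ± 0.20. A second TEF probe gave −0.36, and the TEF probes averaged −1.11, with the call kept. A second NR1D1 probe gave −0.53 and was not called. CLOCK (−0.98 ± 0.11), the activating subunit, and PER3 (−0.87 ± 0.12) also fell and were chosen after their values were seen. Camera called no shift (adjusted p = 0.379, median 0.10, within-slide medians −0.02, 0.26 and −0.06). Of 29 genes of the unfolded protein and integrated stress responses, 5 rose and 2 fell (5 and 2 when adjusted over the list alone, 5 to 6 and 1 to 5 over the scalings). DDIT4, an inhibitor of mTOR, rose by 2.67 ± 0.17, CEBPB, a leucine zipper factor, by 1.08 ± 0.17 and the stress kinase EIF2AK3 by 1.05 ± 0.14, and TRIB3 fell (−0.94 ± 0.20), a call lost with slide as a block and on leaving out any 1 array but dexamethasone replicate 3 (−1.02 to −0.81). The sensor ERN1 (1.28 ± 0.29) lost its call on leaving out any 1 array but dexamethasone replicate 3 (1.11 to 1.30) and when probes were averaged (0.44). DNAJB9 (0.86 ± 0.19; 0.75 to 0.88 without any 1 array but ethanol replicate 3) and ATF4 (−0.51 ± 0.14; −0.53 to −0.38 without any 1 array but ethanol replicate 1), both chosen after their values were seen, lost their calls in those fits, and ATF4 also with slide as a block and with probes averaged. A shift of these genes was not called (camera, adjusted p = 0.319, median 0.02, within-slide medians 0.11, 0.21 and −0.05). Of 25 heat shock genes, 5 rose and 1 fell (5 and 1 when adjusted over the list alone). HSPA2 rose by 3.55 ± 0.26, HSPA6 by 1.42 ± 0.21, both members of the same chaperone family, CRYAB, a small heat shock protein, by 1.79 ± 0.20 and HSPH1 by 1.09 ± 0.19. DNAJB6 (0.78 ± 0.08) rose and CHORDC1 (−0.52 ± 0.13) fell, both chosen after their values were seen, and CHORDC1 lost its call with slide as a block and on leaving out any 1 array but ethanol replicate 3 (−0.57 to −0.44). Further DNAJB6 probes gave 0.82, 0.71 and 0.01, the last not called. As a list, their shift was not called (camera, adjusted p = 0.218, median 0.04, within-slide medians −0.08, 0.02 and 0.11).

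Wnt and Notch genes were lowered more often than raised, with 6 of 36 raised, 13 lowered and 17 not called (7 and 15 when adjusted over the list alone). The Notch ligand JAG1 rose by 2.41 ± 0.20, FZD8, a Wnt receptor, by 2.23 ± 0.27, and the Notch ligand DLL1 at least 25.7-fold from a level not well above background on any ethanol array. RNF43 fell. No shift of the list was called (camera, adjusted p = 0.611, within-slide medians −0.09, −0.09 and −0.10), and its median (−0.07) and mean (0.02) differed in sign. Of 36 genes of the TGF-beta and BMP pathway, 5 rose and 6 fell (5 and 7 when adjusted over the list alone). TGFBR3, a co-receptor, rose by 3.66 ± 0.31, and the matricellular proteins CCN1 and CCN2 by 1.85 ± 0.26 and 2.92 ± 0.42, with CCN2 well above background on 1 of 3 ethanol arrays. TGIF1 (0.92 ± 0.15) and ID1 (1.54 ± 0.30) rose and were chosen after their values were seen, and ID1 lost its call without dexamethasone replicate 1 or 2 (1.42 to 1.44). BAMBI, a decoy receptor (−1.75 ± 0.36), lost its call without ethanol replicate 1 or 2 (−1.62 to −1.59). The shift of the whole list was not called (camera, downward, adjusted p = 0.744, median −0.15 but mean 0.06, within-slide medians −0.17, −0.11 and −0.06). Of 46 adhesion, junction and matrix genes, 8 rose and 7 fell (11 and 12 when adjusted over the list alone). COL4A2, a basement membrane collagen, rose by 5.12 ± 0.27 and CLDN8, a tight junction protein, by 3.86 ± 0.15, whereas the integrin ITGA2 fell by 2.36 ± 0.13. Camera called no shift (upward, adjusted p = 0.985, median −0.11 but mean 0.18, within-slide medians −0.14, −0.18 and 0.03).

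**Figure D3:**
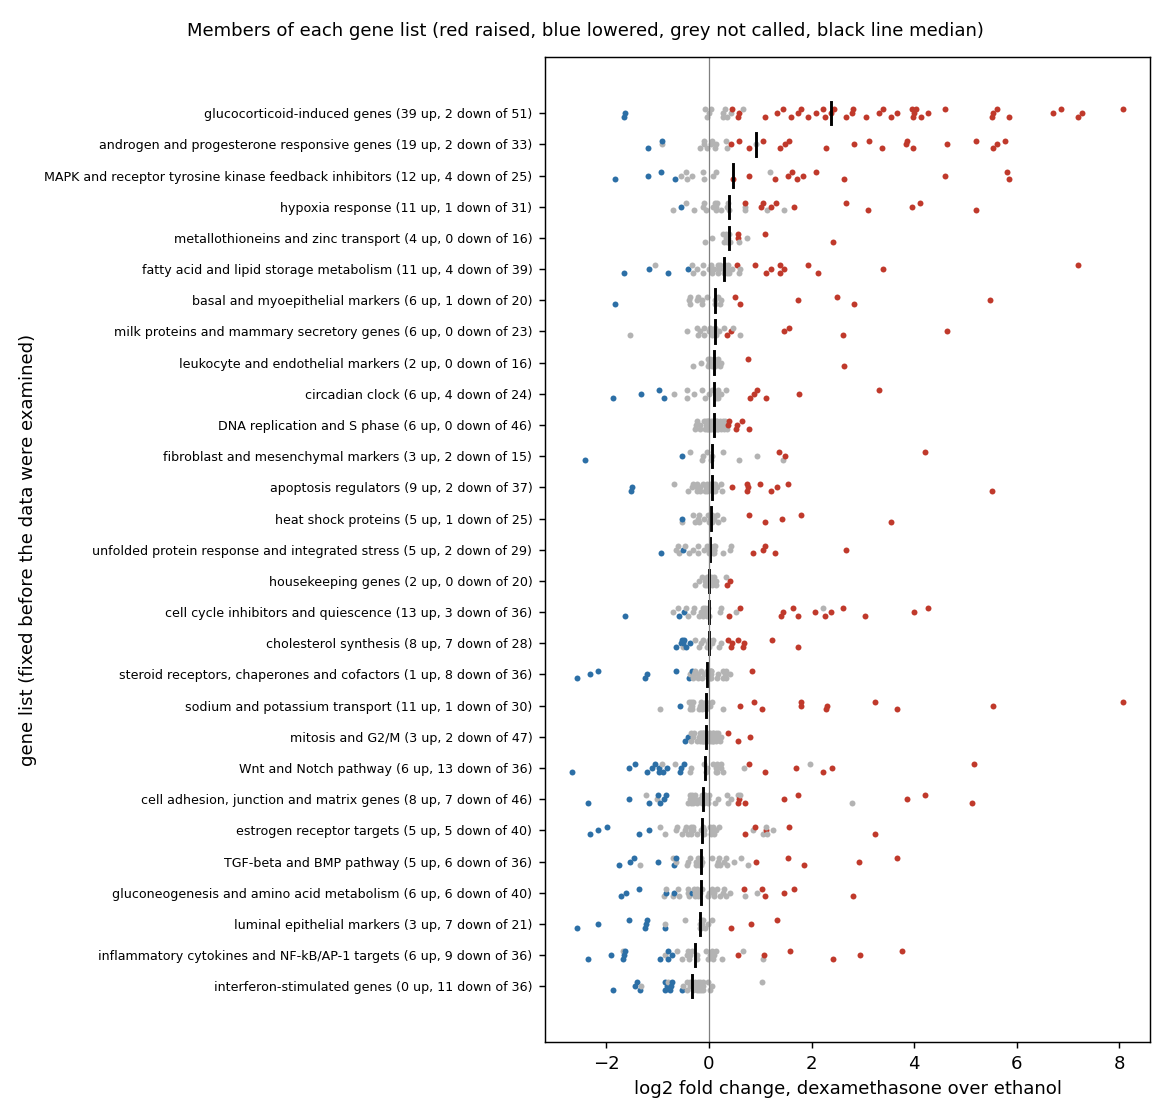
Each point is 1 tested member of 1 of 29 gene lists, with its log2 fold change (dexamethasone over ethanol, 3 arrays each) on the horizontal axis, raised members in red, lowered in blue, the rest in grey and the list's median as a black line. The glucocorticoid-induced list has the highest median (2.38) and the interferon-stimulated list the lowest (−0.34); counts of small changes, such as those of cholesterol synthesis genes, move with the scaling.

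Of 20 housekeeping genes, 2 rose and 0 fell, while 0 were called when adjusted over the list alone and 0 with spike-in scaling, and 3 rose and 1 fell with quantile normalization. ACTB and GAPDH were not called (0.07 ± 0.08 and −0.04 ± 0.10). Among the raised members, HPRT1 (0.36 ± 0.09) lost its call with slide as a block and on leaving out any 1 array but ethanol replicate 3 (0.31 to 0.38). A shift of these genes was not called (camera, adjusted p = 0.393, median 0.01, within-slide medians −0.07, 0.15 and 0.05). With slide as a block, the lists not called above had an adjusted p of 0.24 to 0.975, apart from the luminal markers.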

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

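Scaling to spike-in probes was the 1 alternative chosen after the data were seen, and the others were planned. Of the summary counts (changed, raised, lowered, at least 2-fold, lists shifted), 68 values under the alternatives that kept all arrays lay within 1.5-fold of the reported ones and 5 did not. The 68 include those from the authors' table, which holds the same values, so its agreement was fixed in advance. Normexp background correction gave 1259 genes changed at least 2-fold in place of 1963. That fit changed the signal, the background correction, the offset and the normalization together, and which of these lowered the count was not tested. With slide as a block, 1714 genes were lowered in place of 2708, with 1897 raised and 3473 of the 3611 called genes shared with those reported; the cause was not tested. A 1.5-fold threshold gave 3671 genes, and an adjusted p of 0.01 gave 2323, by construction. With the correlation between genes of a list estimated from the data, 0 of 29 lists were called in place of 11, and 7 had an unadjusted p under 0.05. That form of the test also has fewer degrees of freedom, so the lost calls do not by themselves show that members move together. Leaving out 1 array gave 2718 to 6086 changed, 1508 to 2837 raised and 1197 to 3249 lowered genes, each lowest without an ethanol array and highest without dexamethasone replicate 3, and 1660 to 2392 changed at least 2-fold. Spike-in scaling gave 5158 changed genes, 1763 raised and 3395 lowered, and the authors' table of values gave the same results as the scanner values. No called gene changed direction between the fits compared (0 opposite calls). Of the 179 named genes, 167 were called and 136 kept their call without each array in turn; the most calls lost in 1 fit with all arrays was 21, with slide as a block, before 14 with no filter on dim probes. Averaging a gene's probes moved 11 of the 179 by over 1.5-fold and ended 7 calls. Another probe stood for HRH1 without the dim filter (fitted value −1.55) and without ethanol replicate 1 (fitted value −1.84).

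Whether the replicate numbers pair the arrays stayed open. The deviations of same-numbered arrays from their group means correlated across genes at 0.23, −0.04 and 0.19 for numbers 1, 2 and 3, so dexamethasone replicates 1 and 3 matched the ethanol array of their own number best, and dexamethasone replicate 2 matched ethanol replicate 3 best (0.08). That array shares its slide. Dexamethasone replicate 1 matched ethanol replicate 2, on its own slide, almost as well (0.22). Dexamethasone replicate 3 did not match ethanol replicate 1, on its slide (−0.12). Neither number nor slide accounts for all the matches. With the replicate number as a block, 5111 genes changed, 2306 raised and 2805 lowered, 1988 at least 2-fold, and 11 lists shifted. Of the named genes, 9 then lost a call and 2, MYC and KLF7, gained one. Robust eBayes and slide as a random block were not run for the list shifts, for which camera has no such option. Signal over background limits the folds of dim genes: 145 genes raised at least 2-fold had no ethanol array well above background, so their rises have only a lower bound, as had the falls of 26 lowered genes.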

Other observations

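Collagen and keratin genes, on no list of their own, were looked at after the data were seen. Of 35 tested collagen genes 10 rose and 1 fell (COL1A1, −0.52 ± 0.12, not called with slide as a block or on leaving out any 1 array but ethanol replicate 3, −0.53 to −0.45), and over the scalings 9 or 10 rose and 0 or 1 fell. COL6A1, a microfibrillar collagen, rose by 4.59 ± 0.38 and COL2A1, a cartilage collagen, by 3.67 ± 0.15, beside COL4A2 (5.12 ± 0.27). Of 39 genes with the keratin prefix 10 rose under each scaling and 1 or 2 fell, KRT222 (−1.29 ± 0.23) in the reported one. The raised ones included KRT72 (3.51 ± 0.24) and KRT73 (2.54 ± 0.30), which form the inner root sheath of hair. Against all 14958 named genes, of which 1642 were raised and 1695 lowered, Fisher's exact test over 197 families and both directions (394 tests) gave an adjusted p of 0.126 for raised collagen genes and of 0.216 for raised keratin genes, so neither passed. Leaving out arrays was not run for these counts.

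The tests of dexamethasone replicate 3 and of the gene families were chosen after the results were seen, and the regroupings of the arrays were planned. Dexamethasone replicate 3 showed a smaller response than the other dexamethasone arrays. Its median share of the log2 response was taken over a subset of the genes called without it. That share was 0.761 for 1378 raised and 0.666 for 894 lowered genes. Replicates 1 and 2 had 1.07 and 1.11 for raised and 1.08 and 1.06 for lowered genes. The fit without replicate 3 called 2837 raised and 3249 lowered genes, of which 1498 and 894 changed at least 2-fold. The shares thus do not cover all called genes. Ethanol replicate 3 also stood apart, with shares of 0.941 for raised and 0.846 for lowered genes against 1.00 and 1.02 to 1.04 for ethanol replicates 1 and 2, and its deviations correlated with those of dexamethasone replicate 3 at 0.19. Compressed signal is argued against by a slope of 1.03 on the other dexamethasone arrays over 7351 genes with an unadjusted p above 0.5, where the other arrays had 0.949 to 1.02 on their own group. An effect of slide 2 on both its arrays would lift the shares of ethanol replicate 1 above 1 by as much as dexamethasone replicate 3 fell short, and these were 1.00 for raised and 1.04 for lowered genes. RNA without the response mixed into it stays open. It would give equal shares of unresponsive RNA from raised and lowered genes, and these were 0.429 and 0.212 on the linear scale, but the difference of 0.217 (0.122 to 0.368 over the scalings) was no larger, within its interval of 0.181 to 0.238, than that of ethanol replicate 3 (−0.213). Dexamethasone replicate 3 was also the dimmest array, with the lowest median intensity (181), the fewest probes well above background (77.6%), the most spots with a surrogate value (11.6%) and the highest spike-in signal over the 75th percentile (0.90 on the log2 scale, 0.68 to 0.79 on the others). The slope does not bear on a lower yield of RNA or label, which stays open. A weaker or earlier hormone response of that culture may remain as well, and neither of these last was tested.

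Zinc finger genes with the prefix ZNF were seldom raised. Of 411 tested, 11 rose (2.68%) and 60 fell (adjusted p = 1.41e-07 for few raised, 0.528 for lowered), and 9 to 17 rose over the scalings. Brightness is not a likely sole cause, since random sets of genes matched on mean signal had as few raised genes in a share of 0.0001, the smallest the 10000 sets can give, with a median of 45 raised. No biological explanation was tested. Olfactory receptor genes also had few raised members (0 of 91, adjusted p = 0.0111), but they were seldom lowered too (3 of 91, unadjusted p = 0.0117, adjusted p = 0.271), and no sets matched on signal were drawn for them.

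Kruppel-like factor genes were often raised, with 7 of 16 raised (6 to 8 over the scalings) and 1 lowered, but the excess failed the correction over families (adjusted p = 0.112). The raised members were KLF15 (6.70 ± 0.51, 7.29 without ethanol replicate 3, 4.01 with probes averaged), KLF9 (2.79 ± 0.11), KLF4 (2.61 ± 0.28), KLF13 (1.49 ± 0.21, 0.23 at a second probe, 0.86 with probes averaged), KLF6 (1.32 ± 0.17), KLF5 (1.11 ± 0.13) and KLF8 (1.27 ± 0.31, not called with slide as a block or on leaving out any 1 array but dexamethasone replicate 3, 1.08 to 1.36). KLF2 fell (−0.48 ± 0.08), a call lost with probes averaged (−0.27), and KLF7 was not called (0.84 ± 0.24, adjusted p = 0.0537). KLF7 passed without dexamethasone replicate 3 (1.04) and with quantile normalization, median scaling, normexp background correction, probes well above background on all 6 arrays, an intensity trend and the replicate number as a block (adjusted p 0.0112 to 0.0489). Sets matched on mean signal had as many raised genes in a share of 0.0004, with a median of 2, so brightness alone is an unlikely source. No biological explanation was tested, and 3 members were on the glucocorticoid-induced list beforehand.

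Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split, and 1 split in all, gave as many changed genes (5039, highest other 0), raised genes (2331, highest other 0), lowered genes (2708, highest other 0) and genes changed at least 2-fold (1963, highest other 0). Every other split puts arrays of both treatments on each side, so a strong difference between treatments widens the spread within sides. Calls were therefore unlikely in those splits from the start, and their counts of 0 do not measure chance. For the list shifts 3 splits, the real one among them, gave at least 11 lists (highest other 13). The split with 13 lists set dexamethasone replicates 1 and 3 and ethanol replicate 1 against the rest, which keeps both arrays of slides 2 and 3 together. A split with 12 lists set dexamethasone replicates 1 and 3 and ethanol replicate 3 against the rest, with 1 array of each slide on each side. A slide imbalance was thus not needed for a regrouping to call as many lists as the real split. Each other split has unequal numbers of dexamethasone arrays on its sides, so part of the treatment difference stays between them. The list counts of these splits are thus not free of treatment and do not measure chance. The 11 lists of the real split kept their calls with slide as a block. The regroupings cannot show whether that number is unusual.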
